A study of Homo sapiens with 12 samples.

How the data were processed

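Per the labels, total RNA was extracted with trizol, labelled with biotin and hybridized to Illumina bead arrays, with 3 arrays in each of 4 groups. The labels name a smaller BeadChip design than the 47224 probes of the deposited table would need, and which design was used stays open here. Samples were grouped by their titles, and replicate numbers came from the same labels. Per the file headers, the deposited table of the series holds a mean bead signal, an intensity on a linear scale that was neither background-subtracted nor normalized, and a detection p-value for each probe and array. The software behind both is not given in the sources used here. The authors' second table holds processed intensities, found by comparison to be the same signals after quantile normalization on the linear scale: probe order within each array was the same, every column had a median of 439.6, and 99.0% of values were whole multiples of the last decimal of the signals divided by 17 (tolerance 0.02). Means over 17 arrays would give such values, so whether further arrays were normalized with these 12 stays open. That table was used as an alternative only. All 12 arrays were used and 0 columns of samples were left out.

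Signals were corrected with the neqc method of limma 3.58.1 in R 4.3.3, which fits the background from the detection p-values (offset 16), and were quantile normalized and put on the log2 scale. The steps of the detection p-values correspond to 770 negative controls per array. Probes were kept with detection p under 0.0500 on at least 3 arrays (19777 probes). Of all probes 30111 had 1 gene symbol in the platform table, 8 had several and 17105 had none there, and 30072 were brought to current symbols by gene ID. The brightest kept probe stood for a gene, and unnamed probes stayed single, which left 16171 items (11205 named genes and 4966 unnamed probes), of which 8408 were detected on all 12 arrays. Genes with another probe called in the opposite direction are not named.

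A linear model with 4 group means was fitted to all 12 arrays with limma, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment within each comparison, with calls at adjusted p under 0.0500. The comparisons were each group against control, Cas/ErbB2 against ErbB2 and against Cas, the interaction, the items called the same way in all comparisons of Cas/ErbB2, and the sharing between comparisons against control, for which 50 sets of unchanged groups were simulated. Of 33 gene lists 31 had at least 5 measured members and were tested with camera (preset correlation 0.0100, Benjamini-Hochberg over lists and comparisons), with an estimated correlation and the rotation test fry as alternatives. The result of 1 list is not reported here. Named genes are the 10 largest rises and falls per comparison among calls whose 3 arrays did not overlap those of the other group, leaving out provisional symbols, the 10 highest and lowest of the items called in all comparisons of Cas/ErbB2 by their smallest change, the 5 largest interaction terms of each sign, up to 4 called members of each list, and BCAR1, ERBB2 and NGFR. Genes whose call was lost under several alternatives were mostly left out of the text.

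Alternatives were normexp (offset 50) or no background correction, median scaling, the authors' processed intensities, no filter and other detection filters, single probes or probe means per gene, the arrays of a comparison alone, the replicate number as a block, trend and robust moderation, array weights, stricter thresholds and leaving out each array in turn. Added after the data were seen were a filter for detection on all 12 arrays, ErbB2 against Cas, list tests without Cas/ErbB2 replicate 3, and a fit of the 9 arrays without control. The fit was checked on simulated arrays for ErbB2 against control (16171 items, 200 changed), where 6% of changes of 0.5 on the log2 scale, 60% of 1 and 100% of 2 or 3 were recovered, with 7 false among 140 calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.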

Results

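Total RNA of MCF10A cells, a non-tumorigenic human mammary epithelial line, was measured on 12 Illumina bead arrays, 3 for each of 4 groups. The titles call the groups ErbB2, Cas, Cas/ErbB2 and Ctr MCF10A.B2. The last, called control here, is described as modified MCF10A cells like the rest, and what MCF10A.B2 cells carry is not given. ErbB2 is a receptor tyrosine kinase of the EGF receptor family, and p130Cas, the product of BCAR1, a focal adhesion adaptor. Array names mark control M-, ErbB2 M+, Cas C- and Cas/ErbB2 C+. Whether the signs mark states of the same cells, and how either protein was raised or activated, is not given. The series title names an invasive signature dependent on p130Cas and ErbB2, and the comparisons ask which transcripts went with ErbB2 alone, with Cas alone, with both, and with both beyond either. Changes below are log2 differences between group means of normalized signal with the standard error of the limma fit (n = 3 arrays per group), and adjusted p is Benjamini-Hochberg over 16171 items (11205 named genes and 4966 unnamed probes). Where detection failed on part of a group's arrays, the number with detection follows the value, which rests partly on undetected signal. A gene not detected on any array of a group has only a bound there, given as at least N-fold. The bound sets the mean of the other group against the mean, over the undetected arrays, of the higher of the lowest signal detected on that array and the probe's own signal. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. With 3 arrays against 3 the smallest exact permutation p is 0.1, and the number of arrays limits the precision of every value. Comparisons, gene lists and the rule for named genes were fixed before the data were examined.

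Median raw signal was 171 to 202 on the control arrays and 477 to 623 on the other 9. Between 19076 and 19416 probes were detected on control arrays, against 14099 to 15084 on ErbB2, 13897 to 15214 on Cas and 12864 to 15984 on Cas/ErbB2 arrays. Cas/ErbB2 replicate 3 had the highest median (623) and mean signal (2094) of all 12 arrays, and 15984 probes were detected on it against 12864 and 13350 on replicates 1 and 2. Across items, which are not independent replicates, Pearson's r between arrays of a group was 0.987 to 0.992 for control, 0.982 to 0.986 for ErbB2, 0.984 to 0.985 for Cas and 0.962 to 0.980 for Cas/ErbB2. Principal component 1 held 52.7% of the variance and parted the control arrays from the other 9, and component 2 held 13.7%. Per the labels, control replicates 1 and 2 carry hybridization number III, control replicate 3 II and the other arrays none.

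**Figure D1:**
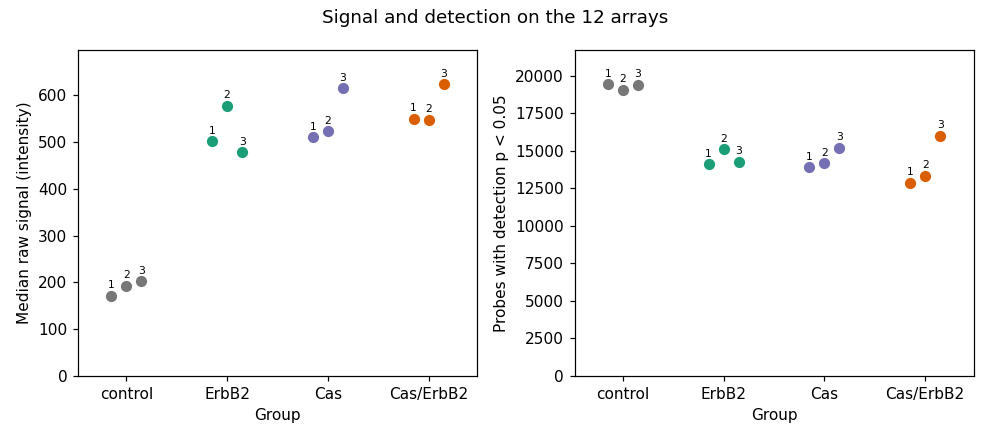
Median raw signal (intensity, left) and number of probes with detection p under 0.05 (right) of each array by group, 1 point per array with its replicate number. The 3 control points lie below the other 9 in signal and above them in detected probes.

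**Figure D2:**
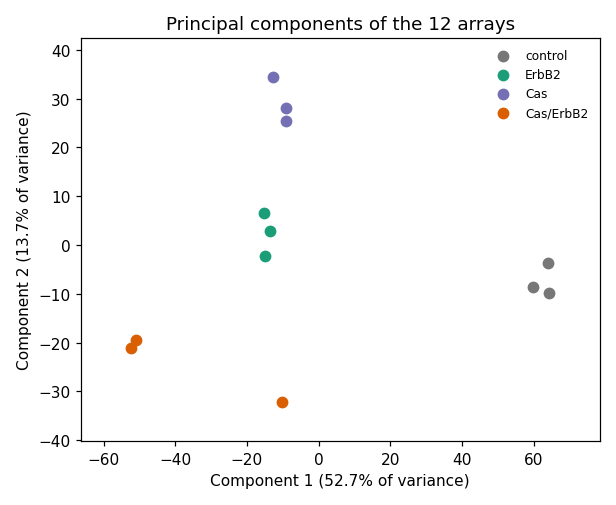
Principal components 1 and 2 of normalized log2 values of the 16171 items (arbitrary units), 1 point per array, coloured by group. The control arrays lie apart along component 1 and Cas/ErbB2 replicate 3 lies away from replicates 1 and 2.

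The BCAR1 probe ILMN_1672596 had a mean log2 signal of 9.59 ± 0.36 (SD, n = 3) in control, 9.26 ± 0.49 in ErbB2, 9.28 ± 0.23 in Cas and 9.10 ± 0.18 in Cas/ErbB2 cells. No comparison of BCAR1 passed (adjusted p = 0.386 for Cas against control and 0.131 for Cas/ErbB2 against control). The ERBB2 probe ILMN_2352131 read 10.22 ± 0.13 in control, 9.85 ± 0.13 in ErbB2, 10.08 ± 0.26 in Cas and 9.05 ± 0.28 in Cas/ErbB2 cells. ERBB2 was lower in Cas/ErbB2 than in control (log2 -1.17 ± 0.17, adjusted p = 2.68e-04), than in Cas (log2 -1.03 ± 0.17, adjusted p = 0.00261) and than in ErbB2 cells (log2 -0.80 ± 0.17, adjusted p = 0.0361). The ERBB2 difference between Cas/ErbB2 and ErbB2 missed the threshold without the detection filter (0.0641), in a fit of these 6 arrays alone (0.193), in a fit of the 9 arrays without control (0.0914) and without ErbB2 replicates 1 (0.123), 2 (0.0835) and 3 (0.101), or Cas replicate 2 (0.0543), or Cas/ErbB2 replicates 1 (0.113) and 2 (0.127), or control replicates 1 (0.0511), 2 (0.0567) and 3 (0.0629), in a range of 0.0048 to 0.193. Of a further pair of ERBB2 probes 1 was detected, on 1 control array only. NGFR, part of an ErbB2 chimera these cells may carry, was not detected on any array. Of these genes 2 of 3 were tested, and in Cas/ErbB2 against control 0 rose, 1 fell and 1 did not pass (0 and 1 adjusted over the list alone). Where these probes lie relative to any introduced sequence is not known here, so they do not check the labels.

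ErbB2 cells were compared with control to see what went with ErbB2 alone. The decoy receptor for FAS ligand TNFRSF6B (log2 3.06 ± 0.18) rose 8.33-fold, and the secreted lipoprotein lipase inhibitor ANGPTL4 (log2 3.00 ± 0.23) rose. Large rises were also seen for MALL (log2 2.93 ± 0.28) and TMEM158 (log2 2.88 ± 0.18), membrane proteins of lipid rafts and of the Ras response. Among others were the prohormone convertase chaperone SCG5 (log2 2.67 ± 0.18), the ecto-nucleotidase NT5E (log2 2.58 ± 0.15), the protease inhibitor SERPINE2 (log2 2.57 ± 0.17), the secreted glycoprotein STC2 (log2 2.49 ± 0.15), DEPP1 (log2 2.42 ± 0.22, 1 of 3 control arrays) and the receptor kinase feedback inhibitor SPRY4 (log2 2.41 ± 0.18). Falls to no detection on all 3 ErbB2 arrays included the growth hormone receptor GHR (at least 4.17-fold lower) and the fatty acid receptor CD36 (at least 3.63-fold lower). Others were ZBED3 (at least 3.35-fold lower), STARD13 (at least 2.77-fold lower) and PPFIBP2 (at least 2.84-fold lower). SELENBP1 (log2 -2.43 ± 0.33, 2 of 3 ErbB2 arrays) and the proline dehydrogenase PRODH (log2 -2.42 ± 0.20) also fell. These genes had adjusted p from 1.09e-06 to 1.93e-04, and the choice of genes required arrays not overlapping those of control. In all 4952 items were called, 2257 higher and 2695 lower (54.4% lower, 63.8% among named genes). Of the sixth of items with the lowest mean signal, 47.5% were called lower (median log2 -0.52), where the raw background of the control arrays lay below that of the others. Of that sixth 82.8% passed the detection filter only with control arrays, which favours falls. Of the rest at most 0.432% were lower and 36.1% to 57.2% higher in comparisons against control. Median scaling, under which the median change over all items was 0.26 in this comparison, 0.20 in Cas and 0.21 in Cas/ErbB2 against control and -0.33 in the interaction (reported medians lay between -0.0364 and 0.0155), called 8072 items, 23.4% lower; 7974 were called without the detection filter and 2552 over items detected on all 12 arrays (42.4% lower).

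Of 22 measured genes of ERK pathway output and feedback, 13 rose, 2 fell and 7 did not pass (18 and 2 adjusted over the list alone), with DUSP6 (log2 2.17 ± 0.13), PHLDA1 (log2 2.20 ± 0.15) and IER3 (log2 1.74 ± 0.16). DUSP6 is a phosphatase of ERK itself and PHLDA1 and IER3 are early response genes. ERK output moved up by camera (adjusted p = 3.56e-06, adjusted p = 0.145 with an estimated correlation). Of 9 measured integrin genes, 4 rose, 0 fell and 5 did not pass (4 and 0 adjusted over the list alone), with ITGA5 (log2 1.30 ± 0.25) and ITGA2 (log2 0.92 ± 0.16). ITGA5 and ITGA2 encode fibronectin and collagen receptor chains. Integrin genes moved up by camera (adjusted p = 0.022, adjusted p = 0.334 with an estimated correlation). Integrin genes missed the threshold with median scaling (0.12) and without the detection filter (0.321), in a range of 0.00786 to 0.321. Of 18 measured inflammatory cytokine and NF-kappaB target genes, 10 rose, 0 fell and 8 did not pass (11 and 1 adjusted over the list alone), with CXCL8 (log2 1.71 ± 0.31), CCL20 (log2 1.69 ± 0.16) and S100A8 (log2 1.23 ± 0.16). Inflammatory genes moved up by camera (adjusted p = 0.00453, adjusted p = 0.302 with an estimated correlation). Median scaling lost this call (0.0674, range 0.00119 to 0.0674). Of 18 measured genes of cholesterol synthesis and uptake, 8 rose, 1 fell and 9 did not pass (9 and 1 adjusted over the list alone), with CYP51A1 (log2 1.39 ± 0.16), IDI1 (log2 1.24 ± 0.13) and MVD (log2 1.07 ± 0.22). All 3 encode enzymes of the mevalonate and sterol pathway. Cholesterol synthesis moved up by camera (adjusted p = 0.00506, adjusted p = 0.292 with an estimated correlation). Median scaling lost this call (0.108, range 1.56e-04 to 0.108).

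Of 24 measured glycolysis and hypoxia response genes, 8 rose, 2 fell and 14 did not pass (9 and 2 adjusted over the list alone), with SLC2A3 (log2 1.97 ± 0.21, 1 of 3 control arrays), NDRG1 (log2 0.98 ± 0.16) and PFKFB4 (log2 0.94 ± 0.22). SLC2A3 is a glucose transporter and NDRG1 a hypoxia-induced gene. Glycolysis and hypoxia moved up by camera (adjusted p = 0.022, adjusted p = 0.353 with an estimated correlation). Glycolysis and hypoxia missed the threshold with median scaling (0.400), without the detection filter (0.0824), over genes detected on all 12 arrays (0.0804) and without ErbB2 replicate 2 (0.0537), in a range of 0.0074 to 0.400. Of 30 measured mitosis and G2/M genes, 0 rose, 9 fell and 21 did not pass (0 and 10 adjusted over the list alone), with KIF2C (log2 -1.39 ± 0.34, 2 of 3 ErbB2 arrays), KIF20A (log2 -0.91 ± 0.17) and NUSAP1 (log2 -0.80 ± 0.19). KIF2C and KIF20A are mitotic kinesins and NUSAP1 is a spindle protein. Mitosis genes moved down by camera (adjusted p = 0.00388, adjusted p = 0.559 with an estimated correlation). Of 13 measured NRF2 target genes of the oxidative stress response, 0 rose, 7 fell and 6 did not pass (0 and 8 adjusted over the list alone), with ALDH3A1 (log2 -2.42 ± 0.12), AKR1B10 (log2 -0.91 ± 0.22) and AKR1C3 (log2 -0.89 ± 0.17). These encode aldehyde and carbonyl detoxifying enzymes. NRF2 targets moved down by camera (adjusted p = 0.00506, adjusted p = 0.163 with an estimated correlation). Matrix proteases did not pass as a list, though the gelatinase MMP9 (log2 2.12 ± 0.32) and ADAM19 (log2 2.04 ± 0.15) rose. The ligand TGFA (log2 1.36 ± 0.19) rose and its receptor EGFR (log2 -1.09 ± 0.13) fell. In the amino acid response TRIB3 (log2 2.18 ± 0.16) and ASNS (log2 1.33 ± 0.20) rose while DDIT3 (log2 -1.68 ± 0.26, 2 of 3 ErbB2 arrays) fell.

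Cas cells were compared with control to see what went with Cas alone. The 3456 items shared with ErbB2 against control, and the hybridization of the control arrays, limit this comparison in the same way. The siderophore-binding lipocalin LCN2 (log2 2.72 ± 0.38) rose 6.57-fold and the antimicrobial S100 protein S100A7 (log2 2.48 ± 0.35) 5.58-fold. The cornified envelope genes SPRR2F (log2 2.56 ± 0.25) and SPRR2A (log2 2.33 ± 0.42, 2 of 3 control arrays), the gelatinase MMP9 (log2 2.45 ± 0.32) and the chemokines CXCL8 (log2 2.41 ± 0.31) and CCL5 (log2 2.16 ± 0.17) also rose, as did COXFA4L3 (log2 2.59 ± 0.25) and S100P (log2 2.21 ± 0.34) and the haemoglobin chaperone AHSP (at least 2.85-fold higher). Falls, to no detection on all 3 Cas arrays unless stated, included RHOBTB3 (at least 2.65-fold lower), HRCT1 (at least 3.46-fold lower) and STARD13 (at least 2.75-fold lower) and the stress transcription factor DDIT3 (at least 3.50-fold lower). Further falls were those of EPHB6 (at least 1.94-fold lower), ZBED3 (at least 3.33-fold lower) and MYOT (at least 2.02-fold lower), the kinesin KIF4A (at least 2.64-fold lower), TRAM2 (at least 2.29-fold lower) and the organic anion pump ABCC2 (log2 -2.13 ± 0.20, 1 of 3 Cas arrays). The 20 genes, chosen likewise, had adjusted p from 4.88e-06 to 0.00153. Of all items 4742 were called, 2165 higher and 2577 lower (54.3% lower, 66.0% among named genes). The dimmest sixth of items again held the highest share of falls (50.1% called lower, median log2 -0.58). With median scaling 7470 items were called (22.3% lower), without the detection filter 8164, and over items detected on all 12 arrays 1776 (37.7% lower).

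Among inflammatory cytokine and NF-kappaB target genes, 9 rose, 0 fell and 9 did not pass (11 and 1 adjusted over the list alone) of 18 measured, with CXCL8, S100A8 (log2 1.09 ± 0.16) and S100A9 (log2 1.19 ± 0.17). S100A8 and S100A9 form the calcium-binding complex calprotectin. Inflammatory genes shifted up by camera (adjusted p = 0.00593, adjusted p = 0.315 with an estimated correlation). Inflammatory genes missed the threshold with median scaling (0.0824) and without the detection filter (0.0715), in a range of 3.80e-04 to 0.0824. Among squamous differentiation genes, 9 rose, 1 fell and 5 did not pass (9 and 1 adjusted over the list alone) of 15 measured, with S100A7, KRT13 (log2 2.02 ± 0.27, 2 of 3 control arrays) and KLK5 (log2 1.97 ± 0.29). KRT13 is a keratin of stratified mucosa and KLK5 an epidermal protease. Squamous genes shifted up by camera (adjusted p = 0.00744, adjusted p = 0.426 with an estimated correlation). Squamous genes missed the threshold with median scaling (0.0674) and without the detection filter (0.194), in a range of 0.00136 to 0.194. Among luminal mammary markers, 5 rose, 0 fell and 5 did not pass (5 and 0 adjusted over the list alone) of 10 measured, with CD24 (log2 1.00 ± 0.23) and KIT (at least 1.57-fold higher, 2 of 3 Cas arrays). Luminal markers shifted up by camera (adjusted p = 0.022, adjusted p = 0.373 with an estimated correlation). Luminal markers missed the threshold with median scaling (0.0721), without the detection filter (0.11), over genes detected on all 12 arrays (0.0881) and without Cas replicate 2 (0.0643), in a range of 0.00939 to 0.11. Among ERK output and feedback genes, 6 rose, 2 fell and 14 did not pass (10 and 3 adjusted over the list alone) of 22 measured, with DUSP6 (log2 1.63 ± 0.13) and IER3 (log2 1.24 ± 0.16). ERK output shifted up by camera (adjusted p = 0.0187, adjusted p = 0.334 with an estimated correlation). ERK output missed the threshold with median scaling (0.245) and without Cas replicate 2 (0.0789), in a range of 0.00258 to 0.245. Among mitosis and G2/M genes, 0 rose, 9 fell and 21 did not pass (0 and 9 adjusted over the list alone) of 30 measured, with KIF2C (at least 2.86-fold lower), AURKB (log2 -0.74 ± 0.18) and KIF20A (log2 -0.67 ± 0.17). AURKB is a kinase of the chromosomal passenger complex. Mitosis genes shifted down by camera (adjusted p = 0.00561, adjusted p = 0.577 with an estimated correlation). Outside these lists the cell adhesion molecule EPCAM (log2 1.04 ± 0.14) and the coagulation initiator F3 (log2 1.61 ± 0.18) rose. The receptors EGFR (log2 -1.03 ± 0.13) and AXL (log2 -0.98 ± 0.13), the Rac exchange factor DOCK1 (log2 -1.05 ± 0.19) and the collagen crosslinker LOX (at least 1.51-fold lower) fell.

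ErbB2 was also set directly against Cas, a comparison added after the data were seen. In ErbB2 cells 174 items were higher than in Cas cells and 76 lower. Higher in ErbB2 cells were SCG5 (log2 2.47, adjusted p = 6.35e-05), NT5E (log2 2.36, adjusted p = 1.41e-05), SERPINE2 (log2 2.12, adjusted p = 9.68e-05), SPRY4 (log2 1.57, adjusted p = 0.00105) and ASNS (log2 1.86, adjusted p = 6.48e-04). ALDH3A1 (log2 -1.56, adjusted p = 8.97e-05) was lower. No difference passed for LCN2 (log2 -1.52, adjusted p = 0.0899), COXFA4L3 (log2 -1.04, adjusted p = 0.0681), S100A7 (log2 -0.33, adjusted p = 0.828) and CXCL8 (log2 -0.71, adjusted p = 0.431), which had risen in Cas cells. Items higher in ErbB2 than control and than Cas numbered 130 (24.3 for independent lists), and items lower than both 66 (12.7). For Cas, 9 were higher than control and than ErbB2 (10.2 for independent lists) and 59 lower than both (27.7). In 50 simulations of unchanged groups the mean number shared was 0, which sets no bound, as such groups have almost no calls to share. Each pair of comparisons shares the ErbB2 or the Cas arrays, so part of any excess may come from them. The count fell from 250 to 145 in a fit of the 9 arrays without control. It was 158, 138 and 136 without ErbB2 replicates 1, 2 and 3. Without Cas replicates 1 and 3 it was 127 and 142, and without Cas/ErbB2 replicate 3 it was 378.

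Cas/ErbB2 cells were compared with control to see what went with both together. The limit set by the hybridization of the control arrays holds here too. The angiopoietin receptor TEK (at least 21.0-fold higher) and the transsulfuration enzyme CBS (at least 11.2-fold higher), neither detected on any control array, had the largest bounds among the rises given here. TMEM158 (log2 4.15 ± 0.18) rose 17.7-fold. The glucose transporter SLC2A3 (log2 3.87 ± 0.21, 1 of 3 control arrays) and the actin-bundling inositol phosphate kinase ITPKA (log2 3.73 ± 0.26) also rose, and so did SCG5 (log2 3.92 ± 0.18), MALL (log2 3.83 ± 0.28), STC2 (log2 3.76 ± 0.15), SERPINE2 (log2 3.72 ± 0.17) and NT5E (log2 3.70 ± 0.15). Among the falls were those of the proline dehydrogenase PRODH (at least 9.48-fold lower), the carnitine synthesis enzyme BBOX1 (log2 -3.84 ± 0.31, 1 of 3 Cas/ErbB2 arrays) and the epithelial calmodulin-like gene CALML3 (at least 5.54-fold lower). Others were RAB7B (log2 -3.68 ± 0.25, 1 of 3 Cas/ErbB2 arrays), GHR (at least 3.96-fold lower), ABCC2 (at least 3.79-fold lower) and CD36 (at least 3.44-fold lower), the Notch glycosyltransferase LFNG (log2 -3.28 ± 0.33, 1 of 3 Cas/ErbB2 arrays), CHN1 (log2 -3.27 ± 0.35, 1 of 3 Cas/ErbB2 arrays) and the aldehyde dehydrogenase ALDH3A1 (log2 -3.24 ± 0.12). These 20 genes had adjusted p from 4.11e-08 to 1.95e-05. In total 7355 items were called, 3389 higher and 3966 lower (53.9% lower, 62.7% among named genes). In the dimmest sixth of items 49.7% were called lower, with a median log2 of -0.54. The count was 11129 without the detection filter and 3691 over items detected on all 12 arrays, and 30.8% of the calls were lower with median scaling.

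ERK output and feedback genes had 22 members measured, of which 15 rose, 2 fell and 5 did not pass (17 and 2 adjusted over the list alone), with SPRY4 (log2 3.64 ± 0.18), PHLDA1 (log2 3.04 ± 0.15) and DUSP6 (log2 2.49 ± 0.13). ERK output moved up by camera (adjusted p = 4.53e-07, adjusted p = 0.145 with an estimated correlation). Integrin genes had 9 members measured, of which 7 rose, 0 fell and 2 did not pass (7 and 0 adjusted over the list alone), with ITGA5 (log2 2.49 ± 0.25) and ITGB5 (log2 1.37 ± 0.12). Integrin genes moved up by camera (adjusted p = 5.17e-04, adjusted p = 0.204 with an estimated correlation). Genes of the amino acid and unfolded protein response had 20 members measured, of which 13 rose, 3 fell and 4 did not pass (13 and 5 adjusted over the list alone), with TRIB3 (log2 3.06 ± 0.16), ASNS (log2 2.79 ± 0.20), PHGDH (log2 2.72 ± 0.17) and XBP1 (log2 2.17 ± 0.15). ASNS makes asparagine, PHGDH begins serine synthesis and XBP1 is a transcription factor of the unfolded protein response. Amino acid response moved up by camera (adjusted p = 0.00937, adjusted p = 0.145 with an estimated correlation). Amino acid response missed the threshold with median scaling (0.422), in a range of 0.00278 to 0.422. Glycolysis and hypoxia response genes had 24 members measured, of which 10 rose, 2 fell and 12 did not pass (10 and 2 adjusted over the list alone), with SLC2A3 and NDRG1 (log2 1.47 ± 0.16). Glycolysis and hypoxia moved up by camera (adjusted p = 0.00986, adjusted p = 0.334 with an estimated correlation). Glycolysis and hypoxia missed the threshold with median scaling (0.497) and over genes detected on all 12 arrays (0.0709), in a range of 0.00274 to 0.497.

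Mitosis and G2/M genes had 30 members measured, of which 0 rose, 24 fell and 6 did not pass (0 and 24 adjusted over the list alone), with KIF2C (at least 2.73-fold lower), AURKB (log2 -1.63 ± 0.18) and KIF20A (log2 -1.63 ± 0.17). Mitosis genes moved down by camera (adjusted p = 2.29e-07, adjusted p = 0.334 with an estimated correlation). DNA replication and G1/S genes had 24 members measured, of which 2 rose, 16 fell and 6 did not pass (2 and 16 adjusted over the list alone), with TK1 (log2 -2.89 ± 0.29, 1 of 3 Cas/ErbB2 arrays) and POLA1 (at least 1.65-fold lower). TK1 is thymidine kinase and POLA1 a polymerase subunit. DNA replication moved down by camera (adjusted p = 0.0029, adjusted p = 0.344 with an estimated correlation). Interferon-stimulated genes had 26 members measured, of which 3 rose, 15 fell and 8 did not pass (4 and 16 adjusted over the list alone), with ISG15 (at least 2.77-fold lower) and ISG20 (log2 2.72 ± 0.18). Interferon-stimulated genes moved down by camera (adjusted p = 0.00739, adjusted p = 0.287 with an estimated correlation). Interferon-stimulated genes missed the threshold over genes detected on all 12 arrays (0.685), in a range of 1.66e-04 to 0.685. Antigen presentation genes had 14 members measured, of which 1 rose, 8 fell and 5 did not pass (1 and 8 adjusted over the list alone), with TAP1 (log2 -1.44 ± 0.15) and PSMB8 (log2 -1.19 ± 0.22). TAP1 is a peptide transporter and PSMB8 an immunoproteasome subunit. Antigen presentation moved down by camera (adjusted p = 0.0114, adjusted p = 0.204 with an estimated correlation). Among genes of other lists the stromelysin MMP10 (at least 4.59-fold higher), the laminin chain LAMB3 (log2 1.89 ± 0.15), the Notch target HEY1 (log2 2.64 ± 0.16) and the repressor PRDM1 (log2 2.66 ± 0.19) rose. The desmosomal genes DSC3 (log2 -1.40 ± 0.16) and DSG3 (log2 -1.04 ± 0.16) fell.

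Cas/ErbB2 was compared with ErbB2 to see what went with Cas on top of ErbB2. The angiopoietin receptor TEK (log2 2.48 ± 0.15) was 5.59-fold higher and the actin-bundling kinase ITPKA (log2 2.90 ± 0.26) 7.47-fold higher. CBS (log2 2.94 ± 0.25, 1 of 3 ErbB2 arrays), the Notch target HEY1 (log2 2.24 ± 0.16, 2 of 3 ErbB2 arrays), the repressor PRDM1 (log2 2.01 ± 0.19), the trypsinogen PRSS3 (log2 1.82 ± 0.21, 2 of 3 ErbB2 arrays) and the serine synthesis enzyme PHGDH (log2 1.71 ± 0.17) rose with them (adjusted p from 4.01e-05 to 0.00191). Falls that passed in every setting in which they were tested (with detection on all 12 arrays SAA1 alone was), apart from stricter thresholds, were those of the helicase subunit MCM2 (at least 1.95-fold lower), the polymerase subunit POLR2L (at least 1.71-fold lower), the acute phase proteins SAA1 (log2 -1.73 ± 0.14) and SAA2 (at least 1.20-fold lower) and KCNIP3 (at least 1.55-fold lower). Other rises were those of the glucose transporter SLC2A3 (log2 1.90 ± 0.21), CHGB (at least 2.17-fold higher) and CNTN3 (at least 2.99-fold higher), NT5E (log2 1.11 ± 0.15) and SERPINE2 (log2 1.15 ± 0.17). Other falls were those of TYMSOS (log2 -2.32 ± 0.32, 1 of 3 Cas/ErbB2 arrays) and ADORA2B (log2 -2.26 ± 0.35, 2 of 3 Cas/ErbB2 arrays), thymidine kinase TK1 (log2 -2.13 ± 0.29, 1 of 3 Cas/ErbB2 arrays), S100A7 (log2 -1.98 ± 0.35), RAB7B (log2 -1.94 ± 0.25, 1 of 3 Cas/ErbB2 arrays), CALML3 (at least 1.58-fold lower) and CXCL16 (log2 -1.90 ± 0.25, 1 of 3 Cas/ErbB2 arrays) and IFI27 (log2 -1.79 ± 0.30, 2 of 3 Cas/ErbB2 arrays). Of all items 419 were called, 187 higher and 232 lower (55.4% lower).

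In ERK output and feedback genes, of 22 measured, 4 rose, 0 fell and 18 did not pass (8 and 0 adjusted over the list alone), with SPRY4 (log2 1.23 ± 0.18) and SPRY2 (log2 1.02 ± 0.12). ERK output shifted up by camera (adjusted p = 9.42e-07, adjusted p = 0.145 with an estimated correlation). In amino acid and unfolded protein response genes, of 20 measured, 6 rose, 0 fell and 14 did not pass (14 and 0 adjusted over the list alone), with PHGDH, ASNS (log2 1.47 ± 0.20), PSAT1 (log2 1.21 ± 0.15) and XBP1 (log2 0.92 ± 0.15). Amino acid response shifted up by camera (adjusted p = 1.06e-10, adjusted p = 0.0107 with an estimated correlation). In DNA replication and G1/S genes, of 24 measured, 0 rose, 7 fell and 17 did not pass (0 and 12 adjusted over the list alone), with TK1, MCM2 and TYMS (log2 -0.90 ± 0.11). DNA replication shifted down by camera (adjusted p = 4.68e-10, adjusted p = 0.145 with an estimated correlation). In mitosis and G2/M genes, of 30 measured, 0 rose, 4 fell and 26 did not pass (0 and 18 adjusted over the list alone), with AURKB (log2 -1.29 ± 0.18). Mitosis genes shifted down by camera (adjusted p = 2.34e-11, adjusted p = 0.278 with an estimated correlation). In matrix protease and inhibitor genes, of 20 measured, 6 rose, 1 fell and 13 did not pass (10 and 2 adjusted over the list alone), with SERPINE2. Matrix proteases shifted up by camera (adjusted p = 1.89e-04, adjusted p = 0.185 with an estimated correlation).

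Integrin genes (1 rose, 0 fell and 8 not passed of 9, 7 and 0 adjusted over the list alone) shifted up by camera (adjusted p = 1.32e-05, adjusted p = 0.145 with an estimated correlation). Focal adhesion genes (0 rose, 0 fell and 25 not passed of 25, 1 and 0 adjusted over the list alone) shifted up by camera (adjusted p = 0.00983, adjusted p = 0.278 with an estimated correlation). Focal adhesion genes missed the threshold with median scaling (0.121), in a range of 0.00436 to 0.121. Mesenchymal genes (1 rose, 0 fell and 20 not passed of 21, 3 and 1 adjusted over the list alone) shifted up by camera (adjusted p = 0.0471, adjusted p = 0.204 with an estimated correlation). Mesenchymal genes missed the threshold with median scaling (0.0878), without the detection filter (0.231) and without ErbB2 replicates 2 (0.09997) and 3 (0.0554), or Cas replicates 1 (0.0511) and 3 (0.056), or Cas/ErbB2 replicates 2 (0.129) and 3 (0.0625), in a range of 0.0144 to 0.231. Basement membrane genes (1 rose, 0 fell and 6 not passed of 7, 1 and 0 adjusted over the list alone) shifted up by camera (adjusted p = 0.00719, adjusted p = 0.334 with an estimated correlation). Glycolysis and hypoxia genes (1 rose, 0 fell and 23 not passed of 24, 3 and 0 adjusted over the list alone, with SLC2A3) shifted up by camera (adjusted p = 0.0254, adjusted p = 0.367 with an estimated correlation). They missed the threshold with median scaling (0.565), over genes detected on all 12 arrays (0.219) and without ErbB2 replicate 1 (0.057), or Cas/ErbB2 replicates 1 (0.0818) and 2 (0.0901), in a range of 0.0115 to 0.565. Interferon-stimulated genes (1 rose, 1 fell and 24 not passed of 26, 1 and 2 adjusted over the list alone, with IFI27) shifted down by camera (adjusted p = 0.00173, adjusted p = 0.204 with an estimated correlation). They missed the threshold over genes detected on all 12 arrays (0.727), in a range of 1.83e-05 to 0.727. Antigen presentation genes (0 rose, 2 fell and 12 not passed of 14, 0 and 3 adjusted over the list alone) shifted down by camera (adjusted p = 0.0101, adjusted p = 0.204 with an estimated correlation). They missed the threshold without Cas/ErbB2 replicate 3 (0.0922), in a range of 0.00318 to 0.0922. Cholesterol synthesis genes (0 rose, 1 fell and 17 not passed of 18, 0 and 1 adjusted over the list alone) shifted down by camera (adjusted p = 0.0168, adjusted p = 0.334 with an estimated correlation). They missed the threshold over genes detected on all 12 arrays (0.0597) and without ErbB2 replicate 3 (0.0742), or Cas/ErbB2 replicates 1 (0.0573) and 3 (0.118), in a range of 6.59e-04 to 0.118. Ribosome biogenesis genes (0 rose, 0 fell and 18 not passed of 18, 0 and 0 adjusted over the list alone) shifted down by camera (adjusted p = 0.0342, adjusted p = 0.204 with an estimated correlation). They missed the threshold with detection p under 0.01 required (0.0619), with detection required on all 3 arrays of a group (0.0514), over genes detected on all 12 arrays (0.0519) and without ErbB2 replicate 1 (0.0671), or Cas/ErbB2 replicate 3 (0.203), in a range of 0.0025 to 0.203. Squamous genes (1 rose, 3 fell and 11 not passed of 15, 1 and 6 adjusted over the list alone, with S100A7) shifted down by camera (adjusted p = 0.00497, adjusted p = 0.421 with an estimated correlation). Squamous genes missed the threshold without Cas/ErbB2 replicate 3 (0.0838), in a range of 6.48e-05 to 0.0838.

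In a fit of the 6 ErbB2 and Cas/ErbB2 arrays alone 22 items were called (40.9% lower), and 8 of the 20 largest named changes passed. SLC2A3, CHGB, CNTN3, ASNS, PSAT1, SPRY4, SPRY2, SERPINE2, NT5E, XBP1, TYMSOS, ADORA2B, TK1, S100A7, RAB7B, CALML3, CXCL16, AURKB, TYMS, IFI27, AOX1, TGM2 and PRR7 did not pass in that fit, with adjusted p from 0.0513 to 0.127. A fit of the 9 arrays without control called 158, median scaling 277 (65.3% lower) and no detection filter 239. Without Cas/ErbB2 replicate 3 the count was 1642 (68.8% lower). It was 207 without Cas/ErbB2 replicate 1, 194 without Cas/ErbB2 replicate 2, 174 without ErbB2 replicate 1, 153 without ErbB2 replicate 2, 226 without ErbB2 replicate 3, 246 without control replicate 2 and 258 without control replicate 3.

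**Figure D3:**
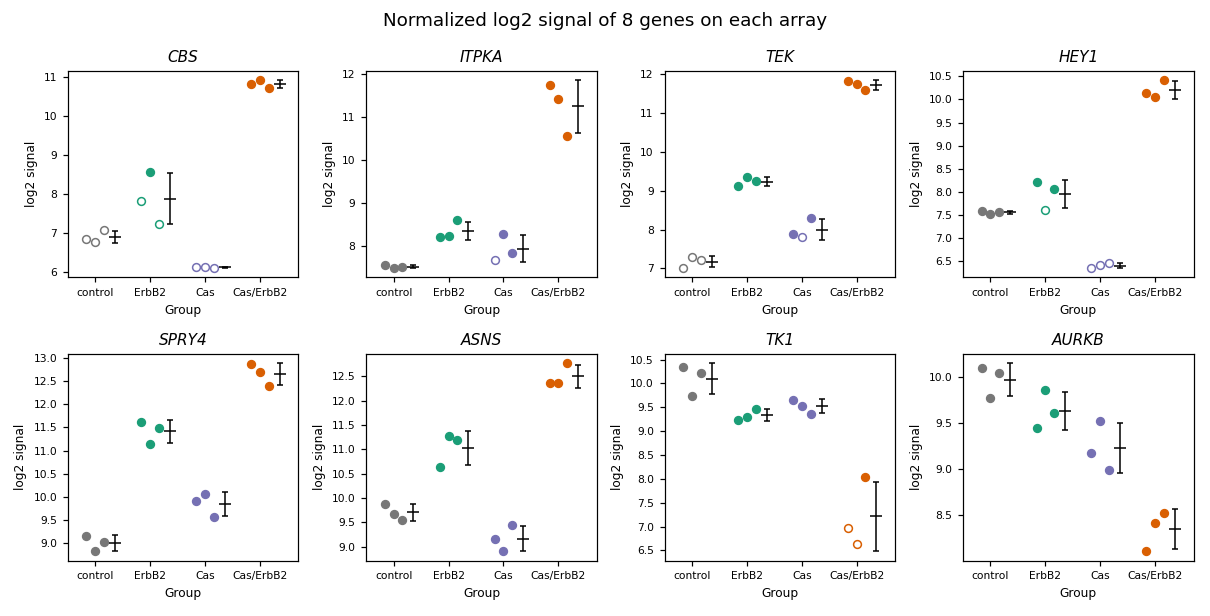
Normalized log2 signal of CBS, ITPKA, TEK, HEY1, SPRY4, ASNS, TK1 and AURKB in the 4 groups. Points are single arrays (open where detection p was 0.05 or more), bars the mean ± SD of 3 arrays, and axes do not start at 0; the 3 Cas/ErbB2 points of CBS, detected on all 3 arrays, lie above those of every other group, where CBS was detected on 1 of 3 ErbB2 arrays and on no control or Cas array.

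Cas/ErbB2 was compared with Cas to see what went with ErbB2 on top of Cas. Several genes undetected on all 3 Cas arrays were detected on all 3 Cas/ErbB2 arrays. They were the Ras-response membrane protein TMEM158 (at least 18.6-fold higher), SLC2A3 (at least 9.14-fold higher), CBS (at least 8.14-fold higher), PRDM1 (at least 6.71-fold higher) and HEY1 (at least 5.34-fold higher), the secreted VSTM2L (at least 7.41-fold higher) and the aldehyde oxidase AOX1 (at least 4.97-fold higher). TEK (log2 3.72 ± 0.15, 2 of 3 Cas arrays) and SCG5 (log2 3.72 ± 0.18) and the spindle orientation adaptor INSC (log2 3.61 ± 0.19) rose as well. Falls were seen in CALML3 (at least 6.17-fold lower), BBOX1 (log2 -3.18 ± 0.31, 1 of 3 Cas/ErbB2 arrays), the fatty acid binding protein FABP4 (at least 2.72-fold lower), the mucosal keratin KRT13 (at least 3.23-fold lower) and PRODH (at least 4.39-fold lower). Complement C3 (log2 -2.78 ± 0.22, 1 of 3 Cas/ErbB2 arrays), RAB7B (log2 -2.77 ± 0.25, 1 of 3 Cas/ErbB2 arrays) and IL32 (at least 2.85-fold lower) fell too, as did the interferon-induced genes IFI27 (log2 -2.67 ± 0.30, 2 of 3 Cas/ErbB2 arrays) and GBP2 (log2 -2.56 ± 0.29, 1 of 3 Cas/ErbB2 arrays). The 20 genes had adjusted p from 6.10e-08 to 3.30e-04. Calls numbered 1677, 784 higher and 893 lower (53.2% lower). A fit of these 6 arrays alone called 768, and 1099 were called without Cas replicate 1.

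ERK output and feedback genes (13 rose, 0 fell and 9 not passed of 22, 14 and 0 adjusted over the list alone) moved up by camera (adjusted p = 2.34e-11, adjusted p = 0.0782 with an estimated correlation), with SPRY4 (log2 2.80 ± 0.18) and PHLDA1 (log2 2.09 ± 0.15). ErbB family genes (3 rose, 0 fell and 6 not passed of 9, 4 and 1 adjusted over the list alone) moved up by camera (adjusted p = 0.0227, adjusted p = 0.204 with an estimated correlation), with TGFA (log2 1.42 ± 0.19), HBEGF (log2 1.32 ± 0.22, 1 of 3 Cas arrays) and ERRFI1 (log2 1.01 ± 0.13). TGFA and HBEGF are ligands and ERRFI1 a feedback inhibitor of the EGF receptor. ErbB family genes missed the threshold without Cas/ErbB2 replicate 3 (0.113), in a range of 0.0096 to 0.113. Integrin genes (7 rose, 0 fell and 2 not passed of 9, 8 and 0 adjusted over the list alone) moved up by camera (adjusted p = 7.84e-08, adjusted p = 0.145 with an estimated correlation), with ITGA5 (log2 2.80 ± 0.25) and ITGB4 (log2 1.25 ± 0.21). Focal adhesion and Cas family genes (5 rose, 0 fell and 20 not passed of 25, 7 and 0 adjusted over the list alone) moved up by camera (adjusted p = 0.00497, adjusted p = 0.204 with an estimated correlation), with BCAR3 (log2 1.07 ± 0.15).

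Matrix protease and inhibitor genes (8 rose, 2 fell and 10 not passed of 20, 9 and 3 adjusted over the list alone) moved up by camera (adjusted p = 0.00144, adjusted p = 0.204 with an estimated correlation), with MMP1 (at least 2.56-fold higher), SERPINE2 (log2 3.28 ± 0.17) and MMP7 (at least 1.79-fold lower). MMP1 is interstitial collagenase and MMP7 matrilysin. Mesenchymal genes (8 rose, 1 fell and 12 not passed of 21, 11 and 2 adjusted over the list alone) moved up by camera (adjusted p = 0.0141, adjusted p = 0.145 with an estimated correlation), with COL4A1 (at least 2.49-fold higher), THBS1 (log2 2.12 ± 0.23) and TAGLN (log2 -2.42 ± 0.30, 2 of 3 Cas/ErbB2 arrays). COL4A1 is a basement membrane collagen and TAGLN an actin-binding protein. Basement membrane and hemidesmosome genes (1 rose, 0 fell and 6 not passed of 7, 3 and 1 adjusted over the list alone) moved up by camera (adjusted p = 0.0423, adjusted p = 0.426 with an estimated correlation), with LAMB3 (log2 1.96 ± 0.15). Basement membrane missed the threshold over genes detected on all 12 arrays (0.0616) and without Cas replicates 1 (0.061) and 3 (0.0906), or Cas/ErbB2 replicate 1 (0.11), in a range of 0.017 to 0.11. Amino acid and unfolded protein response genes (13 rose, 1 fell and 6 not passed of 20, 14 and 1 adjusted over the list alone) moved up by camera (adjusted p = 8.40e-09, adjusted p = 0.0117 with an estimated correlation), with ASNS (log2 3.33 ± 0.20) and PHGDH (log2 2.84 ± 0.17). Glycolysis and hypoxia response genes (11 rose, 0 fell and 13 not passed of 24, 12 and 1 adjusted over the list alone) moved up by camera (adjusted p = 5.34e-07, adjusted p = 0.145 with an estimated correlation), with SLC2A3 and PFKFB4 (log2 1.70 ± 0.22).

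Fatty acid synthesis genes (5 rose, 0 fell and 5 not passed of 10, 6 and 0 adjusted over the list alone) moved up by camera (adjusted p = 4.98e-05, adjusted p = 0.163 with an estimated correlation), with ACSS2 (log2 1.07 ± 0.12) and ME1 (log2 1.06 ± 0.16). DNA replication and G1/S genes (0 rose, 13 fell and 11 not passed of 24, 0 and 13 adjusted over the list alone) moved down by camera (adjusted p = 4.31e-10, adjusted p = 0.145 with an estimated correlation), with TK1 (log2 -2.31 ± 0.29, 1 of 3 Cas/ErbB2 arrays) and MCM2 (at least 2.33-fold lower). Mitosis and G2/M genes (0 rose, 12 fell and 18 not passed of 30, 0 and 13 adjusted over the list alone) moved down by camera (adjusted p = 1.04e-08, adjusted p = 0.323 with an estimated correlation), with KIF20A (log2 -0.96 ± 0.17) and CDC20 (log2 -0.91 ± 0.19). Interferon-stimulated genes (1 rose, 12 fell and 13 not passed of 26, 2 and 15 adjusted over the list alone) moved down by camera (adjusted p = 1.16e-05, adjusted p = 0.145 with an estimated correlation), with ISG15 (at least 2.07-fold lower) and IFI27. Interferon-stimulated genes missed the threshold over genes detected on all 12 arrays (0.341), in a range of 3.23e-09 to 0.341. Antigen presentation genes (0 rose, 6 fell and 8 not passed of 14, 1 and 8 adjusted over the list alone) moved down by camera (adjusted p = 0.002, adjusted p = 0.148 with an estimated correlation), with TAP1 (log2 -1.19 ± 0.15) and HLA-B (log2 -1.07 ± 0.15). Squamous differentiation genes (1 rose, 8 fell and 6 not passed of 15, 2 and 9 adjusted over the list alone) moved down by camera (adjusted p = 0.00561, adjusted p = 0.426 with an estimated correlation), with KRT13, KLK7 (log2 -2.55 ± 0.42, 1 of 3 Cas/ErbB2 arrays) and TGM2 (at least 2.48-fold higher).

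**Figure D4:**
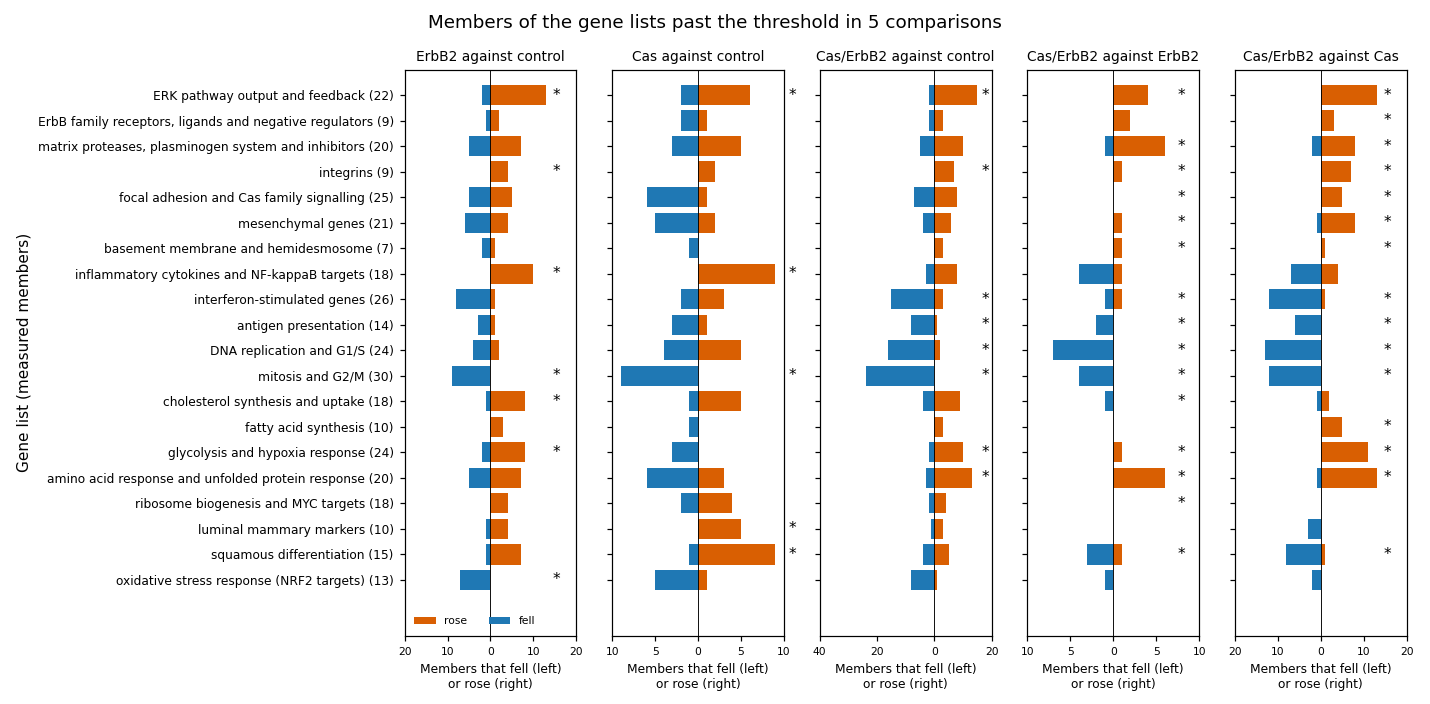
Number of members of each gene list (measured members in parentheses) that rose (right of 0) or fell (left of 0) at adjusted p under 0.05 in 5 comparisons, for lists reported here that were past the threshold by camera with its preset correlation in at least 1 of them. Stars mark those list tests, and the scale differs between panels; of 30 mitosis and G2/M genes 24 fell in Cas/ErbB2 against control.

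A signature of Cas/ErbB2 was taken as the items called the same way in Cas/ErbB2 against control, against ErbB2 and against Cas. It held 356 items, 165 higher and 191 lower, among them 136 and 172 named genes. TEK, ITPKA, CBS, HEY1, PRDM1, PRSS3, PHGDH, SLC2A3, AOX1 and TGM2 were the 10 highest by the smallest of the 3 changes. Against ErbB2 AOX1 (log2 1.56 ± 0.24) and TGM2 (log2 1.56 ± 0.20, 1 of 3 ErbB2 arrays) rose, and PRSS3 (at least 4.01-fold higher) and TGM2 (at least 2.48-fold higher) were undetected on Cas arrays. TYMSOS, ADORA2B, TK1, CALML3, CXCL16, RAB7B, KCNIP3 and, given against ErbB2, PRR7 (log2 -1.84 ± 0.30, 1 of 3 Cas/ErbB2 arrays) were among the 10 lowest. Items higher in Cas/ErbB2 than in ErbB2 and than in Cas numbered 175, against 9.07 for independent lists, and items lower than both 202, against 12.8. The at most 0.0200 items (mean) shared by simulated unchanged groups again set no bound. These comparisons share the Cas/ErbB2 arrays, so part of the excess may come from them. The signature held 20 items when each comparison was fitted on its own 6 arrays and 203 without the detection filter. It held 1086, 178 and 167 without Cas/ErbB2 replicates 3, 1 and 2. It held 152, 134 and 193 without ErbB2 replicates 1, 2 and 3, and 210 and 216 without control replicates 2 and 3.

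The 3 comparisons against control were set side by side to see how far they had genes in common. Altogether 3168 items were called the same way in all 3, 1280 higher and 1888 lower (648 and 1564 named genes). Among them were the rises of DUSP6, IER3, CXCL8, F3 and TEK and the falls of EGFR, ABCC2, KIF2C, KIF20A and POLA1. In ErbB2 cells F3 (log2 1.94 ± 0.18) rose and POLA1 (at least 1.74-fold lower) fell. Called the same way were 3456 items in ErbB2 and Cas, 4364 in ErbB2 and Cas/ErbB2 and 3821 in Cas and Cas/ErbB2, with 18, 8 and 61 called in opposite directions. Independent lists of these sizes would share 302, 473 and 454 higher and 429, 661 and 632 lower, against 1463, 1889 and 1655 higher and 1993, 2475 and 2166 lower observed. Across items r of the changes was 0.884, 0.900 and 0.806, where unchanged groups simulated against the same controls gave 0.500, 0.499 and 0.499. Their 0 shared calls (50 simulations) again set no bound. The covariance was 0.371, 0.468 and 0.420 against 0.0245 simulated in each. The 3 controls are too few to split, so part of the excess may come from the shared controls, whose background lay below that of all other arrays. The number called in all 3 was 6306 with median scaling (19.0% lower, against 59.6%), 5211 without the detection filter and 1220 over items detected on all 12 arrays (36.1% lower).

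The interaction asks whether the change with ErbB2 differed between groups titled with and without Cas. Its log2 differences of differences include the control arrays. The most negative terms were those of S100A7 (log2 -4.46 ± 0.49), KLK7 (log2 -3.53 ± 0.59), COXFA4L3 (log2 -3.49 ± 0.35), LCN2 (log2 -3.45 ± 0.54) and IGFL1 (log2 -3.37 ± 0.37). The most positive were those of CBS (log2 3.72 ± 0.36), CNTN3 (log2 3.57 ± 0.32), HEY1 (log2 3.39 ± 0.22), AOX1 (log2 3.37 ± 0.34) and VSTM2L (log2 3.29 ± 0.28). The latter were undetected on all Cas arrays, so these terms are fitted values and no bounds. The 10 genes had adjusted p from 6.86e-05 to 0.00184. Of all items 2350 were called, 1483 positive and 867 negative (36.9% negative, 27.8% among named genes), and 1045 of the positive calls lay in the dimmest sixth of items. Median scaling called 5638, 84.2% negative, and 782 were called over items detected on all 12 arrays, 65.9% negative.

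Squamous differentiation genes (1 positive, 8 negative and 6 not passed of 15, 1 and 10 adjusted over the list alone) had a negative shift by camera (adjusted p = 4.94e-05, adjusted p = 0.315 with an estimated correlation), with KLK5 (log2 -2.97 ± 0.41) and SPRR2A (log2 -2.70 ± 0.59). Inflammatory genes (3 positive, 8 negative and 7 not passed of 18, 3 and 8 adjusted over the list alone) had a negative shift by camera (adjusted p = 0.00672, adjusted p = 0.315 with an estimated correlation), with SAA1 (log2 -2.60 ± 0.20) and IL32 (log2 -2.55 ± 0.47). Inflammatory genes missed the threshold with median scaling (0.0772) and without the detection filter (0.0555), in a range of 2.64e-04 to 0.0772. Luminal mammary markers (0 positive, 4 negative and 6 not passed of 10, 0 and 5 adjusted over the list alone) had a negative shift by camera (adjusted p = 0.0177, adjusted p = 0.353 with an estimated correlation), with CD24 (log2 -1.69 ± 0.33) and MUC1 (log2 -1.60 ± 0.28). Luminal markers missed the threshold without Cas/ErbB2 replicate 3 (0.102), in a range of 0.00879 to 0.102. DNA replication and G1/S genes (1 positive, 13 negative and 10 not passed of 24, 2 and 16 adjusted over the list alone) had a negative shift by camera (adjusted p = 4.94e-05, adjusted p = 0.29 with an estimated correlation), with MCM2 (log2 -1.70 ± 0.30). DNA replication missed the threshold with median scaling (0.0597), in a range of 1.23e-07 to 0.0597. Cholesterol synthesis and uptake genes (1 positive, 3 negative and 14 not passed of 18, 1 and 5 adjusted over the list alone) had a negative shift by camera (adjusted p = 0.0248, adjusted p = 0.334 with an estimated correlation), with FDPS (log2 -1.06 ± 0.26) and HMGCS1 (log2 -0.88 ± 0.20). Cholesterol synthesis missed the threshold with median scaling (0.235) and without Cas/ErbB2 replicate 1 (0.067), in a range of 0.00258 to 0.235.

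Amino acid and unfolded protein response genes (8 positive, 0 negative and 12 not passed of 20, 9 and 0 adjusted over the list alone) had a positive shift by camera (adjusted p = 2.18e-05, adjusted p = 0.0509 with an estimated correlation), with DDIT3 (log2 3.26 ± 0.36), PSAT1 (log2 2.01 ± 0.22), ASNS (log2 2.00 ± 0.29) and PHGDH (log2 1.83 ± 0.24). Focal adhesion and Cas family genes (5 positive, 0 negative and 20 not passed of 25, 5 and 0 adjusted over the list alone) had a positive shift by camera (adjusted p = 0.0177, adjusted p = 0.298 with an estimated correlation), with DOCK1 (log2 1.28 ± 0.27) and TNS3 (log2 1.11 ± 0.20). Focal adhesion missed the threshold without Cas replicate 3 (0.0516), in a range of 7.94e-04 to 0.0516. Mesenchymal genes (6 positive, 0 negative and 15 not passed of 21, 6 and 1 adjusted over the list alone) had a positive shift by camera (adjusted p = 0.0489, adjusted p = 0.204 with an estimated correlation), with THBS1 (log2 1.37 ± 0.32) and COL4A1 (log2 1.87 ± 0.33). Mesenchymal genes missed the threshold without the detection filter (0.0519), with detection p under 0.01 required (0.124), with detection required on all 3 arrays of a group (0.108) and without ErbB2 replicate 2 (0.0613), or Cas replicates 1 (0.0606) and 3 (0.0663), or Cas/ErbB2 replicates 1 (0.0539) and 2 (0.109), or control replicates 2 (0.052) and 3 (0.0521), in a range of 0.0144 to 0.124. Ribosome biogenesis and MYC target genes (0 positive, 3 negative and 15 not passed of 18, 0 and 6 adjusted over the list alone) had a negative shift by camera (adjusted p = 0.00836, adjusted p = 0.145 with an estimated correlation). Ribosome biogenesis missed the threshold with median scaling (0.245), in a range of 0.00286 to 0.245. Among genes of other lists MMP9 (log2 -2.56 ± 0.45) and EPCAM (log2 -1.47 ± 0.21) had negative and ITGA5 (log2 1.51 ± 0.35) a positive term. DDIT3 and COL4A1 too were undetected on all Cas arrays, and MCM2 and IL32 on all Cas/ErbB2 arrays.

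Lists that passed camera in no comparison are given here for Cas/ErbB2 against control. In epithelial junctions, 5 rose, 6 fell and 9 did not pass of 20 measured (5 and 7 adjusted over the list alone; camera adjusted p = 0.889), with DSC3 (log2 -1.40 ± 0.16). For the TGF-beta pathway, 6 rose, 2 fell and 5 did not pass of 13 measured (6 and 3 adjusted over the list alone; camera adjusted p = 0.296), with LTBP2 (log2 1.58 ± 0.24), ID1 (log2 1.48 ± 0.17) and ID3 (log2 -1.82 ± 0.13). In YAP and SRF targets, 3 rose, 7 fell and 5 did not pass of 15 measured (3 and 7 adjusted over the list alone; camera adjusted p = 0.181), with F3 (log2 2.17 ± 0.18) and TAGLN (log2 -2.35 ± 0.30, 2 of 3 Cas/ErbB2 arrays). For cell cycle inhibitors and p53 targets, 3 rose, 4 fell and 10 did not pass of 17 measured (3 and 4 adjusted over the list alone; camera adjusted p = 0.682), with GADD45A (log2 1.54 ± 0.17) and SESN1 (log2 -2.36 ± 0.19). In basal and myoepithelial markers, 2 rose, 3 fell and 5 did not pass of 10 measured (3 and 6 adjusted over the list alone; camera adjusted p = 0.818), with KRT15 (log2 -0.77 ± 0.13) and KRT5 (log2 -0.59 ± 0.14). For semaphorins, plexins and ephrins, 4 rose, 6 fell and 7 did not pass of 17 measured (4 and 6 adjusted over the list alone; camera adjusted p = 0.617), with EFNB2 (log2 1.49 ± 0.19) and EFNA1 (log2 -1.13 ± 0.11). In heat shock proteins, 2 rose, 2 fell and 7 did not pass of 11 measured (2 and 2 adjusted over the list alone; camera adjusted p = 0.963), with HSPA8 (log2 0.61 ± 0.16). Among housekeeping genes, 1 rose, 2 fell and 8 did not pass of 11 measured (1 and 2 adjusted over the list alone; camera adjusted p = 0.888), with HPRT1 (log2 0.64 ± 0.12) and GUSB (log2 -0.51 ± 0.13).

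Median, mean and camera direction differed in sign in 22 of 186 list tests, of which 0 had passed. In ErbB2 against control they were epithelial junctions, basement membrane, TGF-beta, basal markers and housekeeping genes. For Cas against control these included matrix proteases. In Cas/ErbB2 against control they were epithelial junctions, mesenchymal genes, basement membrane, ribosome biogenesis, basal markers and heat shock proteins. For Cas/ErbB2 against ErbB2 these were ErbB family, fibroblast markers and NRF2 targets. In Cas/ErbB2 against Cas they were YAP and SRF targets, p53 targets, basal markers and leukocyte markers. For the interaction of Cas and ErbB2 these were ERK output and leukocyte markers. Of 186 list tests 60 passed with the preset correlation and 2 with an estimated one, those of the amino acid response in Cas/ErbB2 against ErbB2 and against Cas.

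Markers of other cell types were followed too. Of 8 endothelial markers 2 were measured, and TEK and PECAM1 (log2 0.64 ± 0.14) rose in Cas/ErbB2 against control (2 and 0 adjusted over the list alone). In fibroblast markers, 3 rose, 2 fell and 2 did not pass of 7 measured (3 and 2 adjusted over the list alone; camera adjusted p = 0.617), with FAP (log2 0.79 ± 0.17) and DCN (log2 -2.96 ± 0.30, 2 of 3 Cas/ErbB2 arrays). For leukocyte markers, 3 rose, 0 fell and 2 did not pass of 5 measured (3 and 0 adjusted over the list alone; camera adjusted p = 0.102), with CD68 (log2 1.21 ± 0.17). The camera test passed for neither list in any comparison.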

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

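The tests of calls against control by level and by hybridization were chosen after the result was seen. Regrouping the 9 arrays outside control was chosen once regroupings of all 12 were seen. The interaction drew attention because it tests whether the ErbB2 effect differs between groups with and without Cas in their title. In it 2350 items passed. Its largest log2 terms were those of CBS (3.72), CNTN3 (3.57), HEY1 (3.39), AOX1 (3.37) and VSTM2L (3.29) on the positive and S100A7 (-4.46), KLK7 (-3.53), COXFA4L3 (-3.49), LCN2 (-3.45) and IGFL1 (-3.37) on the negative side. Gene lists passed with the preset correlation only. Their median log2 terms (in parentheses over members detected on all 12 arrays) were 0.48 (0.48 over 18) for the amino acid response. For focal adhesion they were 0.27 (0.27 over 21) and for mesenchymal genes 0.19 (0.27 over 11). They were -1.54 (-1.39 over 8) for squamous genes, -0.78 (-1.51 over 10) for inflammatory genes, -0.76 (-0.78 over 13) for DNA replication, -0.62 (-0.62 over 6) for luminal markers, -0.53 (-0.62 over 15) for cholesterol synthesis and -0.44 (-0.45 over 15) for ribosome biogenesis.

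Of 100 drawn regroupings of the 12 arrays, the real one included, 2 called as many interaction terms (highest other 3706), and the regroupings that called many kept the control arrays together (3 of 99, against at most 12 terms with them parted), which points to a structure of the samples. With the control arrays kept and the other 9 regrouped, 44 of 100 gave as many terms as the real groups (highest 4728, median 1985). For the items called the same way in all comparisons against control, 1 of 100 such regroupings reached 3168 (highest other 3087, median 2715). Keeping the control arrays leaves their difference from the rest in every such regrouping, which fixes high counts beforehand, so neither count decides. For the interaction, the control arrays standing apart and a dependence of the ErbB2 effect on Cas cannot be told apart. The same counts over regroupings of all 12 arrays were 1 of 100 (highest other 2717) for sharing, 1 (highest other 0) for the 356 items of the Cas/ErbB2 signature and 2 (highest other 70) for the 60 list tests. With only the other 9 regrouped the highest were 211 (median 0) for the signature and 59 (median 15) for list tests.

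In calls against control, the control arrays' lower background was weighed as a cause. Of items detected on all 12 arrays, 19.3% to 40.2% were called over the 3 comparisons, which argues against the background of dim probes as the whole cause. The share of falls in the dimmest sixth of items was 2.13 to 4.41 times the highest in another sixth. But 82.8% of these items, detected on fewer than 3 arrays outside control, passed the filter only with control arrays. Of those 57.3% to 60.4% fell, and of the rest at most 0.432% fell and 36.1% to 57.2% rose. As detection depends on the change itself, filter, background and real falls cannot be told apart there. A hybridization of the control arrays apart from the rest cannot be told apart from the groups for the 3168 items called in all 3, since no other array carries a hybridization number.

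Splits of 6 arrays into 3 and 3 are 10 in number, too few for a share under 0.05, and 1 of 10, the real one, gave as many calls in each. Real and highest other counts were 4952 and 0 for ErbB2 against control, 4742 and 0 for Cas, 7355 and 0 for Cas/ErbB2, 419 and 26 for Cas/ErbB2 against ErbB2, 1677 and 1 for Cas/ErbB2 against Cas, and 250 and 0 for ErbB2 against Cas.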

How the results depend on the processing

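The filter for detection on all 12 arrays, the fit without control arrays and ErbB2 against Cas were chosen only after the results were seen. Direction and side of the threshold held in 11671 of 12067 checks of 450 named gene results and in 1182 of 1259 checks of 60 list results. A call was lost in 376 of the gene checks (236 on leaving out an array) and 77 of the list checks (37), and was gained in 18 of the gene checks. Reversed was SLC2A3 in Cas against control (1.21 with median scaling) and FAS in the interaction of Cas and ErbB2 (-0.35 with median scaling); the cause was not tested. Counts over 1.5 times from those reported were as follows. Median scaling gave 8072 (ErbB2 against control), 7470 (Cas against control), 277 (Cas/ErbB2 against ErbB2), 5638 (the interaction) and 6306 (sharing). No filter, which tests more items, gave 7974 (ErbB2 against control), 8164 (Cas against control), 11129 (Cas/ErbB2 against control), 239 (Cas/ErbB2 against ErbB2), 203 (the signature) and 5211 (sharing). Detection on all 12 arrays, which tests fewer, gave 2552, 1776 and 3691 (ErbB2, Cas and Cas/ErbB2 against control), 782 (the interaction) and 1220 (sharing). Fitting only the arrays compared gave 22 (Cas/ErbB2 against ErbB2), 768 (Cas/ErbB2 against Cas) and 20 (the signature), trend and robust moderation 697 (Cas/ErbB2 against ErbB2) and 559 (the signature), and array weights 953 (Cas/ErbB2 against ErbB2), 679 (the signature) and 412 (ErbB2 against Cas). Adjusted p under 0.01 left 2757, 2533 and 4714 (ErbB2, Cas and Cas/ErbB2 against control) and 130 and 850 (Cas/ErbB2 against ErbB2 and Cas). It left 1219 (the interaction), 115 (the signature), 1732 (sharing) and 113 (ErbB2 against Cas). Requiring at least 2-fold left 2044, 2174 and 3219 (ErbB2, Cas and Cas/ErbB2 against control) and 172 and 609 (Cas/ErbB2 against ErbB2 and Cas). It left 123 (the signature), 1384 (sharing) and 129 (ErbB2 against Cas). The fit without control arrays gave 158 (Cas/ErbB2 against ErbB2) and 145 (ErbB2 against Cas). With an estimated correlation 2 list tests and by fry 116 passed, where fry does not set a list against other genes. Causes were not tested except where the number of items or arrays differs. Leaving out each array in turn gave 3466 to 5995 for ErbB2 against control, 3227 to 5674 for Cas against control, 5876 to 8187 for Cas/ErbB2 against control, 153 to 1642 for Cas/ErbB2 against ErbB2, 1099 to 2396 for Cas/ErbB2 against Cas, 1716 to 2647 for the interaction, 134 to 1086 for the signature, 2183 to 3923 for sharing, 127 to 378 for ErbB2 against Cas and 54 to 64 for list tests. Where that left a group with 2 arrays, the spread was pooled over all groups. Signal over background limits what can be read: control arrays detect more dim probes than the rest.

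Deviations from group means of same-numbered arrays correlated at -0.0767 to 0.179 over 18 pairs, 6 of them over 0.1, other pairs at -0.222 to 0.0900, and 8 of 12 arrays correlated best with their own number. That is a hint of pairing from the data, but most same-numbered pairs were not over 0.1 and no label says what a number marks, so the numbers were not taken to pair samples. With the replicate number as a block all counts were within 1.5 times of those reported (for Cas/ErbB2 against ErbB2 351 with a fixed and 479 with a random block), and basement membrane in Cas/ErbB2 against Cas had adjusted p = 0.088. With a fixed block ERBB2 in Cas/ErbB2 against ErbB2 had adjusted p = 0.0558 (range 0.0048 to 0.193), one of 12 named gene calls lost. A slide block was not run, as no slide is given, and leaving out control replicate 3 stood in for the hybridization.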

Other observations

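The tests of this part were written before their results were seen. Beyond the comparisons above, members of a few lists moved apart in Cas/ErbB2 cells. The ligand EFNB2 of Eph receptors rose against control while EPHB3 (at least 1.28-fold lower) and EFNA1 fell, and of the BMP and TGF-beta response PMEPA1 (log2 1.36 ± 0.16) and ID1 rose while ID3 fell. Of the luminal keratins KRT8 (log2 -0.81 ± 0.21) fell and KRT7 (log2 1.05 ± 0.22) rose.

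Cas/ErbB2 replicate 3 stood apart from replicates 1 and 2. Its lowest slope along the difference between those replicates and ErbB2 arrays was 0.138 (highest 0.367, bootstrap SD 0.0136), above the -0.107 to 0.107 of ErbB2 arrays put in its place and below the 0.417 to 0.585 of replicates 1 and 2, which argues against a wrongly labelled ErbB2 array, narrowly. Across items, though, it correlated more with ErbB2 arrays (r = 0.972 to 0.978) than with replicates 1 and 2 (0.962 and 0.963), below the 0.982 to 0.986 among ErbB2 arrays, and a mixture with ErbB2 cells was not tested. Among items detected on all 12 arrays its spread from the others of its group was 1.34 times the highest in another group, a value between those set for and against a higher sensitivity to dim probes, so that explanation cannot be told apart from others. No biological explanation was tested, since the design names no difference between replicates.

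A candidate hypothesis is that Cas/ErbB2 cells cycled less than Cas cells, as 13 of 24 DNA replication and 12 of 30 mitosis genes fell. Neither list passed camera with an estimated correlation (adjusted p = 0.145 and 0.323). Over members detected on all 12 arrays the median log2 change was -0.65 for replication and -0.54 for mitosis, and 0 of 10000 random lists of the same size and level were as low, which argues against a loss of dim probes. In replicate 3 alone the medians were -0.67 and -0.39, with at most 18 of 10000 random lists as low, but 1 array gives no spread between arrays, so replicates 1 and 2 as the only carriers stay open. With the preset correlation the highest adjusted p of both lists over 5 normalizations was 1.04e-08. The growth state of the cultures is not given in the labels and stays open, and cycling itself was not measured.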
